A study of Mus musculus with 6 samples.

How the data were processed

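Total RNA of cells labelled HL-1 was made into 6 libraries, 3 control and 3 tachypaced, with a SMARTER mRNA kit and sequenced, per the labels' protocols. The authors deposited a table of FPKM values, fragment numbers scaled to transcript length and to the mapped fragments of the library, with a row per gene name and a column per library. The genome build was GRCm38 (mm10), per the submitters' processing notes. The aligner, the quantifier, the annotation and the strand setting are not given in the sources used here. Of the 23060 row names, 1201 have the MSTRG form that StringTie gives to transcript models without a gene name. FPKM depends on the transcript length and on the assignment of reads to overlapping or near-identical genes, so a gene whose reads were assigned to another model is listed low or at 0. FPKM is also relative to each library's total, so a change in a few abundant genes shifts all others.

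Table columns were matched to samples through the sample descriptions in the labels, and groups and replicate numbers were taken from the sample titles. No 2 libraries held identical values. Depth was sought in the low values: the ratios of low values between libraries did not gather on a common step, with at most 5.05% of them in a bin of 0.05 on the log2 scale, so no depth, confidence interval or detection floor could be given. Gene positions were taken from GENCODE M21 on GRCm38 by gene symbol, which placed 21404 of the 21859 named rows.

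Values were transformed to log2(FPKM + 1), and the 10361 genes with a mean of at least 1 FPKM over the 6 libraries were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend, two-sided, tachypaced minus control, no covariates). P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. An exact permutation test of 3 against 3 libraries cannot give a p below 0.1 and was not used. The same steps were tested on simulated data made from the 10361 genes of the tachypaced against control comparison, with 200 genes changed. They recovered 95.4%, 96.7%, 98% and 95.3% of the genes changed by 0.5, 0.75, 1 and 1.5 on the log2 scale, with 4.08% of calls false, and called 0 lists in 20 simulations without a change. Genes were drawn independently there, while the real lists had estimated inter-gene correlations of up to 0.799. No simulated library was shifted toward the other group, as a control library was in the real data. The simulations therefore cover neither the recovery of genes nor false calls, of lists above all, where genes or whole libraries vary together.

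Before the data were examined, 31 gene lists were written for stress, ion channels, calcium handling, contraction, inflammation, metabolism, proliferation, other cell types and RNA quality. Of their 954 symbols, 941 were in the table. The 28 lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, Benjamini-Hochberg adjusted over the lists. By this test 12 lists passed, and with an estimated correlation 0 passed, the smallest adjusted p being 0.344. By fry, 26 lists passed for change in either direction and 7 for a shift in a common direction. Those 7 were the chemokine, macrophage, mitochondrial genome, ribosomal protein, matrix, potassium channel (adjusted p 0.0399) and calcium handling (0.0495) lists, while cholesterol and fatty acid synthesis (0.0713), proliferation (0.0713) and hypoxia and glycolysis (0.140) did not pass it. Calls within each list were also counted adjusted over the list alone. The 12 identity lists (further myeloid and cardiomyocyte genes, other cell types and ubiquitous genes) were written after the first look at the table and before those genes were looked at.

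The genes named were fixed by a rule set before the data were examined. They are the 12 called genes with the largest increases and the 12 with the largest decreases among those whose groups do not overlap, leaving out predicted models (Gm, Rik, LOC and ENSMUSG names) and pseudogenes, up to 4 called members per list with the largest changes, and a fixed set of cardiac, stress and guidance genes whatever their result. Of the genes this rule names, 1 is not reported here. Genes that only illustrate cell identity were chosen after their values were seen.

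Alternatives fixed before the data were examined were a pseudocount of 0.1, no filter on low values, a minimum mean of 5 FPKM, median of ratios scaling, quantile normalization, rescaling to a common total per library, limma without the trend, robust hyperparameters, an absolute log2 fold change of at least 1, the replicate number as a block and leaving out each library in turn. Library weights estimated by limma, an adjusted p threshold of 0.1 and the estimated inter-gene correlation were added after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for tables and figures.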

Results

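RNA was sequenced from cultures labelled HL-1, a mouse atrial cardiomyocyte line that keeps a contractile phenotype in culture, to ask which transcripts change when the cells are tachypaced. Tachypacing is rapid electrical stimulation, used in culture as a model of the high atrial rate of atrial fibrillation. There were 3 control and 3 tachypaced libraries, and the pacing rate and duration are not given in the labels. Nothing in the labels says whether the replicates were separate cultures, so the p-values below measure only the spread between these libraries, which may be technical. Expression was given as FPKM for 23060 gene names, of which 7068 were at 0 in all 6 libraries. The FPKM values summed to between 411050 and 432244 per library. Read depth is unknown, because FPKM values carry no counts and the low values did not fall on steps that whole reads would give.

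In all 6 libraries, most transcripts that define cardiac muscle were near 0 and many transcripts of macrophages were abundant. Myh6 (atrial myosin heavy chain), Actc1 (cardiac actin), Myl7 (atrial myosin light chain), Nppb (brain natriuretic peptide) and the cardiac transcription factors Nkx2-5 and Gata4 were listed at 0 in every library. Some members of the sarcomere and cardiomyocyte lists were detected in every library, with means over the 6 libraries of 153 FPKM for tropomyosin 1 (Tpm1), 26.2 for Eno3 and 21.7 for Pdlim5, and lower ones of 4.29 for Myom1, 3.40 for cardiac troponin I (Tnni3), 2.27 for Cryab, 1.69 for Hspb7 and 1.48 for Tnnc1. Nppa, the atrial natriuretic peptide, stood at 0.261 ± 0.0866 FPKM in control and 0.162 ± 0.0686 FPKM in tachypaced libraries (SD, n = 3 each). By contrast, Spp1 (osteopontin) stood at 10152 ± 724 FPKM in control libraries. The lysosomal macrophage marker Cd68 stood at 420 ± 24.6, lysozyme Lyz2 at 358 ± 46.4, the colony stimulating factor receptor Csf1r at 95.5 ± 8.09 and the pan-leukocyte gene Ptprc at 41.6 ± 4.96 FPKM in the same libraries. The macrophage genes C1qa, C1qb and Mrc1 were listed at 0 throughout. Over 25 further myeloid genes the library medians ran from 34.2 to 43.5 FPKM, and over 20 further cardiomyocyte genes no library median exceeded 0.005 FPKM. No library median exceeded 0 for lists of T cell, mast cell, epithelial, neuronal, hepatocyte and skeletal muscle genes. The highest library medians were 0.0106 FPKM for B cell, 0.00853 for neutrophil and 0.0336 for dendritic cell genes. Of 50 genes that every cell uses, such as proteasome and RNA polymerase II subunits, 0 had a mean below 0.1 FPKM. The comparison below is therefore between libraries labelled HL-1 whose transcripts are of this kind.

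**Figure D1:**
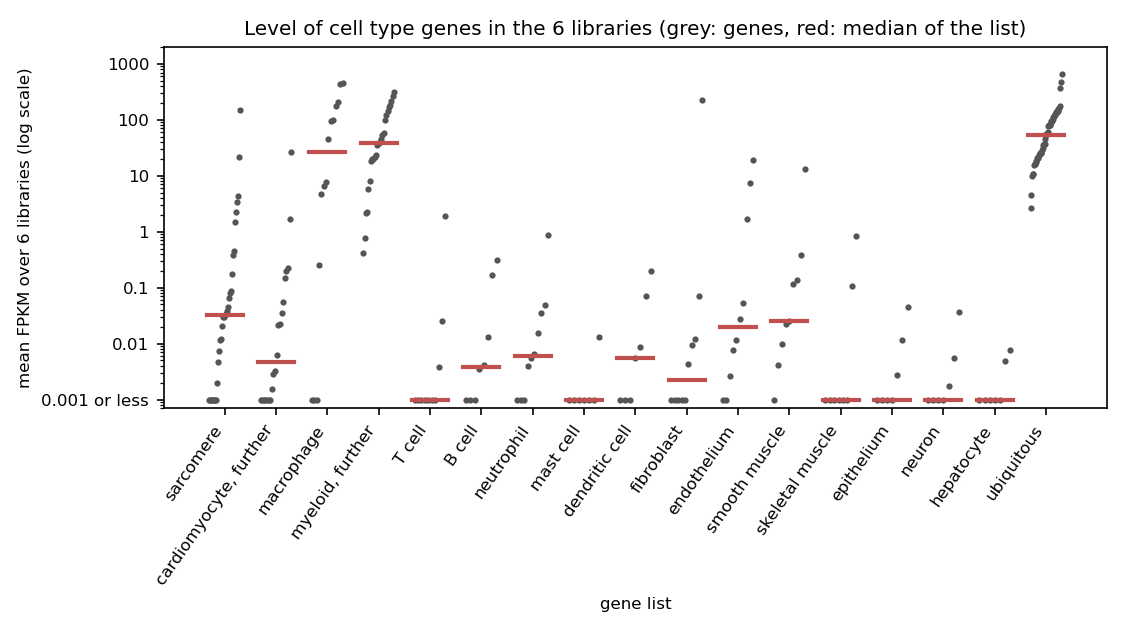
Mean FPKM over the 6 libraries (vertical axis, log scale, values of 0.001 or less drawn at 0.001) of the genes in 17 lists (horizontal axis); grey points are genes and red bars are list medians. The macrophage, further myeloid and ubiquitous lists have their medians above 10 FPKM, and the medians of the other 14 lists lie below 0.1 FPKM.

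In tachypaced libraries 10 of 21 chemokine and cytokine genes rose, and 19 of 33 genes of cholesterol and fatty acid synthesis and 16 of 38 proliferation genes fell. These lists passed a set test with a preset correlation but not with an estimated correlation (adjusted p = 0.344, 0.414 and 0.414 with an estimated correlation). An RNA quality list, of which only histone genes could be tested, also passed the former and not the latter, in the upward direction (adjusted p = 0.000527 and 0.344). The neutrophil chemokine Cxcl3 rose from 0.688, 0 and 0.731 FPKM in the 3 control libraries to 14.2, 15.04 and 12.9 FPKM in the tachypaced libraries. Lcn2 (lipocalin 2, an iron-siderophore binding protein) rose from 12.8 ± 4.38 to 39.8 ± 7.26 FPKM, and Scd2 (a stearoyl-CoA desaturase) fell from 287 ± 85.5 to 145 ± 10.1 FPKM (SD, n = 3 each). Of 10361 genes tested, 238 were higher and 334 lower in tachypaced libraries (limma-trend, Benjamini-Hochberg adjusted p threshold of 0.05). Most changes were small on the log2(FPKM + 1) scale, with a median of 1.31-fold among the called genes. On that scale 6 of them, all higher, reached an absolute log2 fold change of 1, against 11 higher and 2 lower with a pseudocount of 0.1. In all 572 called genes the tachypaced and control values did not overlap, as in 34.9% of the tested genes, against 10% expected by chance for 3 against 3. The 10% is an average over splits of the libraries. Genes that vary together can take the share of a single split far from it, and other splits were not counted.

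Among the called genes, Cxcl3 had the largest increase. The gene (chromosome 5, 90786103 to 90789600, GRCm38) had a log2 fold change of 3.40 (SE 0.19, adjusted p = 0.000254). Lcn2 (chromosome 2, 32384633 to 32388252) rose by 1.60 (SE 0.21) and Csf3, the granulocyte colony stimulating factor (chromosome 11, 98701263 to 98703629), by 1.39 (SE 0.21). Saa3, an acute-phase serum amyloid (chromosome 7, 46711998 to 46715700), rose from 22.5 ± 7.04 to 53.7 ± 7.61 FPKM, a log2 fold change of 1.25 (SE 0.18). Il1rn, the interleukin 1 receptor antagonist, rose from 19.0 ± 4.46 to 37.4 ± 5.59 FPKM. The chemokine genes Ccl3 and Ccl4, neighbours on chromosome 11, rose from 1516 ± 414 to 2864 ± 416 FPKM and from 246 ± 68.6 to 455 ± 49.8 FPKM. The receptor genes Lilr4b and Lilrb4a, near-identical neighbours on chromosome 10 between which reads could be divided either way, had log2 fold changes of 0.95 and 0.92. Fcgr2b, the inhibitory Fc gamma receptor, rose from 4.32 ± 1.56 to 8.42 ± 0.893 FPKM. Cox6a2, the striated muscle isoform of a cytochrome c oxidase subunit, rose from 5.78 ± 1.56 to 13.5 ± 2.69 FPKM. The unnamed gene model MSTRG.8439 rose from 0.235 ± 0.106 to 2.13 ± 1.24 FPKM. Of these 12 genes, those other than Cxcl3 had the same adjusted p of 0.0435.

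Among the genes with the largest decreases, alongside Scd2 (chromosome 19, 44293674 to 44306864, log2 fold change -0.93, SE 0.19), its paralogs Scd3 and Scd4 had log2 fold changes of -0.99 and -0.95. Scd3 fell from 3.60 ± 0.893 to 1.33 ± 0.523 FPKM and Scd4 from 2.71 ± 0.860 to 0.920 ± 0.425 FPKM, low values at which this scale understates the change. Reads shared within this family could be divided between its members. Fasn, the fatty acid synthase (chromosome 11, 120805846 to 120824547), fell from 36.9 ± 8.004 to 20.2 ± 2.71 FPKM. The sterol pathway enzymes Fdps (farnesyl diphosphate synthase), Lss (lanosterol synthase) and Idi1 (isopentenyl diphosphate isomerase) fell from 161 ± 44.3 to 91.5 ± 7.86, from 16.0 ± 4.62 to 8.63 ± 0.714 and from 15.4 ± 3.32 to 8.62 ± 0.737 FPKM. The mitotic kinesin Kif20a fell from 8.82 ± 2.71 to 4.35 ± 0.455 FPKM and the mitotic kinase Aurkb from 23.01 ± 5.83 to 13.4 ± 1.31 FPKM. Rad54l (homologous recombination) and the tubulin gene Tubb4b had log2 fold changes of -0.73 and -0.70. The adjusted p of these genes ran from 0.0435 to 0.0484.

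**Figure D2:**
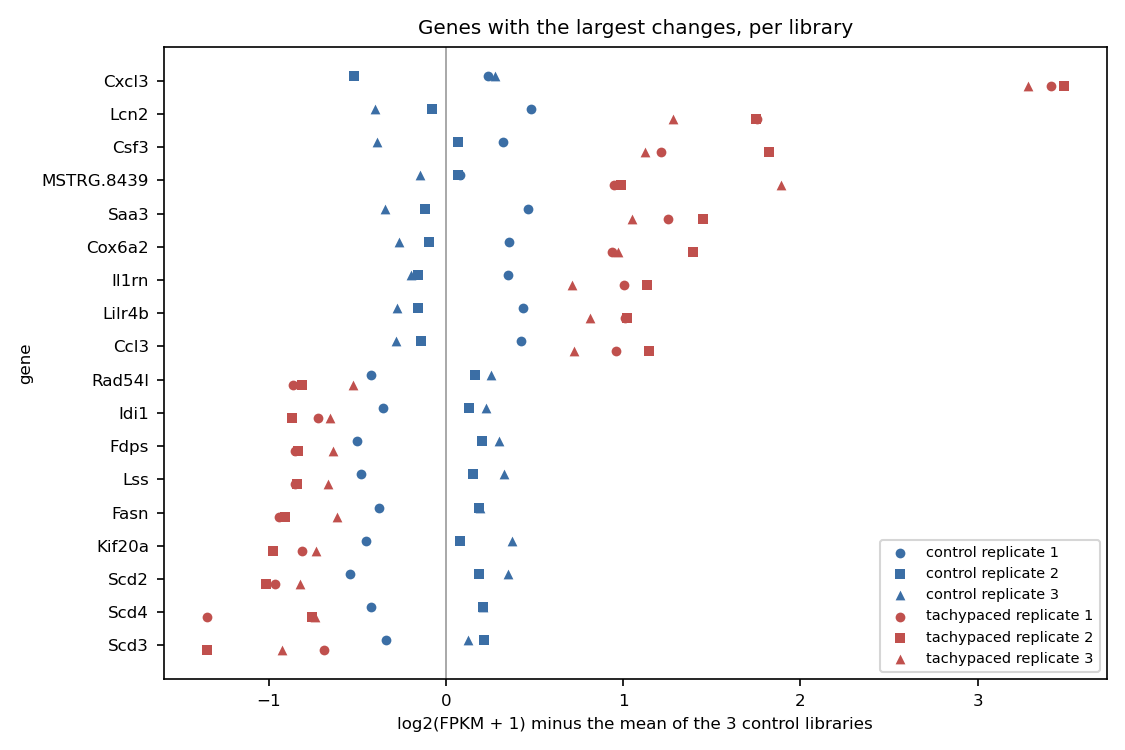
Log2(FPKM + 1) minus the mean of the 3 control libraries (horizontal axis) for the 9 genes with the largest increases and the 9 with the largest decreases (vertical axis); each point is a library, blue for control and red for tachypaced. Cxcl3 lies furthest to the right, with a log2 fold change of 3.40, and control replicate 1 (blue circles) lies between the other controls and the tachypaced libraries for most genes.

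Control replicate 1 stood apart from the other controls. Over 1839 genes that separated the other 2 controls from the tachypaced libraries, its median position was 0.657 on a scale where those controls are 0 and the tachypaced libraries 1. Across genes its correlation with tachypaced replicate 3 was 0.995, against 0.992 and 0.990 with control replicates 2 and 3. The first principal component, with 56.4% of the variance, placed it at 0.04, against -0.47 and -0.62 for the other controls and 0.22 to 0.44 for the tachypaced libraries. Leaving it out removes the control nearest to the tachypaced libraries. The mostly larger counts without it, given with the lists below, are therefore no further support for a list. Leaving out any other library left at most 3 genes higher and at most 1 lower among all tested genes.

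Of 33 tested genes of cholesterol and fatty acid synthesis, 19 fell and 0 rose, or 30 and 0 adjusted over the list alone, with a median log2 fold change of -0.56 and a camera adjusted p of 6.11e-14, which became adjusted p = 0.414 with an estimated correlation. In control replicate 1 the list averaged -0.30 relative to the control mean on the log2 scale, against 0.11 and 0.19 in the other controls, and without this library 30 of the 33 fell.

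Of 38 tested proliferation genes, 16 fell and 0 rose, or 31 and 0 adjusted over the list alone, with a median log2 fold change of -0.36 and a camera adjusted p of 7.57e-12 (adjusted p = 0.414 with an estimated correlation). Besides Kif20a and Aurkb, the mitotic cyclin gene Ccnb2 fell from 34.2 ± 8.06 to 20.5 ± 1.78 FPKM and the kinetochore gene Cenpf from 8.99 ± 1.95 to 5.24 ± 0.473 FPKM. Control replicate 1 averaged -0.19 on this list, against 0.02 and 0.17 in the other controls, and 31 of the 38 fell without it.

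Of 34 tested hypoxia and glycolysis genes, 5 fell and 0 rose, or 16 and 0 adjusted over the list alone, with a camera adjusted p of 1.63e-05 (adjusted p = 0.560 with an estimated correlation). The glycolytic genes Eno1 and Pgk1 fell from 916 ± 117 to 704 ± 7.28 and from 1956 ± 172 to 1567 ± 25.8 FPKM, and Gapdh and Gpi1 had log2 fold changes of -0.36 and -0.26. Control replicate 1 averaged -0.16 here, against 0.07 and 0.10 in the other controls, and 26 of the 34 fell without it.

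Of 21 tested chemokine and cytokine genes, 10 rose and 0 fell, or 13 and 0 adjusted over the list alone, with a median log2 fold change of 0.36 and a camera adjusted p of 1.18e-09 (adjusted p = 0.344 with an estimated correlation). Members past the test beyond those above included Cxcl2, Ccl9, Tnf, Il23a and Spp1, named here after their values were seen. Ccl2, the monocyte chemoattractant, stood at 0.773 ± 0.400 and 1.65 ± 0.397 FPKM and did not pass (adjusted p = 0.0713), and Il6 was at or below 0.0308 FPKM in every library. Control replicate 1 averaged 0.19 on this list, against -0.06 and -0.13 in the other controls, and 14 of the 21 rose without it.

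Macrophage markers rose in 3 of 10 tested genes and fell in 0 (6 and 0 adjusted over the list alone, camera adjusted p = 1.23e-05, and adjusted p = 0.344 with an estimated correlation). These were the endotoxin co-receptor gene Cd14 (82.2 ± 7.84 to 119 ± 9.20 FPKM), Lyz2 (358 ± 46.4 to 503.99 ± 33.3 FPKM) and the cathepsin gene Ctss (152 ± 11.3 to 198 ± 12.1 FPKM); Csf1r stood at 95.5 ± 8.09 and 94.8 ± 3.22 FPKM. Of 30 autophagy and lysosome genes 3 rose and 0 fell (10 and 2 adjusted over the list alone, camera adjusted p = 0.000783, and adjusted p = 0.480 with an estimated correlation). These were the autophagy receptor gene Sqstm1 (416 ± 91.4 to 656 ± 70.6 FPKM) and the cathepsin genes Ctsd and Ctsb, with log2 fold changes of 0.50 and 0.43. Control replicate 1 averaged 0.11 on the macrophage list and 0.09 on the lysosome list, and without it 7 of 10 rose and 0 fell on the former, and 13 of 30 rose and 2 fell on the latter.

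The mitochondrial genome contributed 13 tested genes, of which 3 rose and 0 fell, or 8 and 0 adjusted over the list alone (camera adjusted p = 7.54e-07, and adjusted p = 0.344 with an estimated correlation). These were mt-Co3, mt-Nd3 and mt-Cytb, with log2 fold changes of 0.40, 0.36 and 0.24. Mitochondrial transcripts made up 7.91% to 8.42% of the summed FPKM in control and 9.001% to 9.72% in tachypaced libraries. Of 48 nuclear oxidative phosphorylation genes, 2 rose (Cox6a2 and Uqcrq) and 0 fell, or 2 and 2 adjusted over the list alone, and the list did not pass camera (adjusted p = 0.582). Without control replicate 1, 2 of these rose and 17 fell, and of the 13 mitochondrial genome genes 5 rose and 0 fell. On the mitochondrial genome list control replicate 1 averaged -0.03 relative to the control mean, against 0.01 and 0.02 in the other controls and 0.14 to 0.24 in tachypaced libraries, so here it did not lie toward the latter. Of 68 cytosolic ribosomal protein genes 0 passed in either direction, over all genes or adjusted over the list alone, although at a median log2 fold change of 0.07 the list passed camera (adjusted p = 1.83e-05, and adjusted p = 0.344 with an estimated correlation), and without control replicate 1, which averaged 0.004 against 0.045 to 0.068 in tachypaced libraries, its calls were 6 up and 1 down.

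Among immediate early genes, 1 of 28 rose and 0 fell, and 0 passed adjusted over the list alone (camera adjusted p = 0.000109, and adjusted p = 0.414 with an estimated correlation). This was the stress-responsive transcription factor gene Atf3, at 88.3 ± 9.43 and 112 ± 7.07 FPKM. Fos stood at 5.21 ± 0.105 and 5.001 ± 0.278 FPKM, and Egr1 was below the level tested. Of 29 NF-kB and inflammasome genes 2 rose and 0 fell, and the same numbers passed adjusted over the list alone (camera adjusted p = 0.00402, and adjusted p = 0.344 with an estimated correlation). These were Casp4, an inflammatory caspase, and Ptgs2, cyclooxygenase 2, with log2 fold changes of 0.56 and 0.39. Without control replicate 1, which averaged 0.08 and 0.07 on these lists, 11 of 28 and 12 of 29 rose, and 1 fell on each list.

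Of 6 tested matrix and TGF-beta genes 2 rose and 0 fell, or 3 and 0 adjusted over the list alone (camera adjusted p = 0.0219, and adjusted p = 0.344 with an estimated correlation). They were the gelatinase gene Mmp9 (2.91 ± 0.303 to 4.25 ± 0.253 FPKM) and Tgfb1 (56.5 ± 3.27 to 68.6 ± 3.14 FPKM), and without control replicate 1, which averaged 0.03 against 0.15 to 0.19 in tachypaced libraries, 4 rose and 1 fell and the set test no longer passed (adjusted p = 0.0784). Collagen genes such as Col1a1 and Col3a1 were near or at 0. Of an RNA quality list, 5 genes were tested, all of them histones. Of these 1 rose, H1f2, from 56.4 ± 13.0 to 87.7 ± 11.9 FPKM, and 0 fell, or 4 and 0 adjusted over the list alone (camera adjusted p = 0.000527, and adjusted p = 0.344 with an estimated correlation), and without control replicate 1, 4 rose. Control replicate 1 averaged 0.22 on this list, against 0.00 and -0.22 in the other controls and 0.34 to 0.59 in tachypaced libraries, so it lay between them as on the chemokine, sterol synthesis and proliferation lists.

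**Figure D3:**
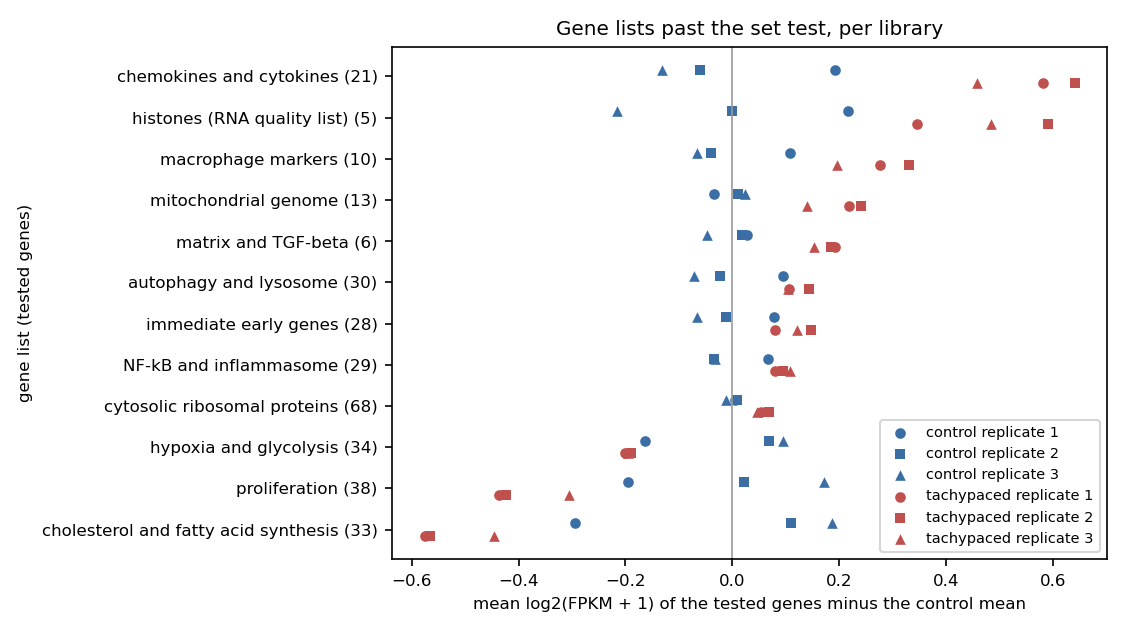
Mean log2(FPKM + 1) of each list's tested genes minus the mean of the 3 control libraries (horizontal axis) for the 12 gene lists that passed camera with its preset correlation (vertical axis, number of tested genes in brackets); each point is a library. Tachypaced libraries lie between -0.58 and -0.45 on the cholesterol and fatty acid synthesis list and between 0.46 and 0.64 on the chemokine list, and control replicate 1 lies at -0.30 and 0.19.

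The electrical and contractile genes for which atrial myocytes are usually studied gave few measurements. Of 33 potassium channel genes 5 could be tested, of which 1 fell, Kcnk6, a two-pore domain channel, from 6.95 ± 0.442 to 5.02 ± 0.246 FPKM, and 0 rose (0 up and 2 down adjusted over the list alone, camera adjusted p = 0.874). Kcnj2, an inward rectifier, stood at 93.3 ± 12.9 and 103 ± 6.07 FPKM (adjusted p = 0.302), and Kcna5 and Kcnj3 were listed at 0 in every library. Of 32 sodium, calcium and pacemaker channel genes 7 could be tested and 0 passed, over all genes or adjusted over the list alone (camera adjusted p = 0.582); Cacna1c stood at 0.195 ± 0.0584 and 0.241 ± 0.0324 FPKM. Of 19 tested calcium handling genes 1 fell, the reticulum calcium binder Calr (566 ± 16.1 to 489 ± 12.6 FPKM), and 0 rose (0 up and 2 down adjusted over the list alone, camera adjusted p = 0.267). Atp2a2, the reticulum calcium pump SERCA2, stood at 103 ± 2.89 and 94.4 ± 2.38 FPKM (adjusted p = 0.123), and Ryr2 was at or below 0.00479 FPKM. Of 32 sarcomere genes 6 could be tested and 0 passed, over all genes or adjusted over the list alone (camera adjusted p = 0.267). Of 7 tested gap junction and intercalated disc genes 1 fell, vinculin (Vcl, 21.1 ± 1.48 to 16.6 ± 1.38 FPKM), and 0 rose (1 up and 1 down adjusted over the list alone, camera adjusted p = 0.962). Gja1 (connexin 43) stood at 0.366 ± 0.126 and 0.305 ± 0.0708 FPKM, and Gja5 was listed at 0 in 5 of 6 libraries. Of 5 tested hypertrophy genes 1 rose, the stress cytokine Gdf15 (10.7 ± 2.67 to 18.0 ± 2.34 FPKM), and 0 fell (1 up and 0 down adjusted over the list alone, camera adjusted p = 0.820). Without control replicate 1, the calls up and down were 1 and 2 for potassium channels, 0 and 1 for sodium and calcium channels, 1 and 5 for calcium handling, 1 and 0 for sarcomere, 1 and 2 for gap junction and 2 and 1 for hypertrophy genes.

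The stress, metabolic and signalling lists that follow did not pass camera. Unfolded protein and integrated stress genes went both ways, with 3 of 33 rising (Gdf15, Cth and Slc7a5) and 3 falling, among them Hsp90b1 at 668 ± 63.0 to 528 ± 29.3 FPKM (5 up and 4 down adjusted over the list alone, camera adjusted p = 0.267). Of 23 heat shock genes 2 fell, the chaperone genes Stip1 and Hsp90ab1, with log2 fold changes of -0.40 and -0.31, and 0 rose (2 up and 4 down adjusted over the list alone, camera adjusted p = 0.414). Of 22 fatty acid oxidation genes 3 rose and 0 fell (3 up and 5 down adjusted over the list alone, camera adjusted p = 0.820). These were the lipid droplet coat gene Plin2 (38.7 ± 6.27 to 64.0 ± 9.22 FPKM), the fatty acid binding protein gene Fabp4 (107 ± 9.46 to 169 ± 18.7 FPKM) and the transporter gene Slc27a1, whose products store or carry lipid and do not oxidise it. Of 29 p53 target and apoptosis genes 1 rose, Gadd45a (log2 fold change 0.73), and 2 fell, Ccng1 and Zmat3 (3 up and 3 down adjusted over the list alone, camera adjusted p = 0.851). Of 13 guidance cue genes 1 fell, the semaphorin receptor Plxnb2 (114 ± 2.01 to 99.0 ± 1.89 FPKM), and 0 rose (0 up and 2 down adjusted over the list alone, camera adjusted p = 0.962); Sema3a was listed at 0 and Ntn1 stood at 0.241 ± 0.0533 and 0.354 ± 0.00612 FPKM. Of 22 interferon-stimulated genes 0 passed over all genes (5 up and 3 down adjusted over the list alone, camera adjusted p = 0.267). None of 27 NRF2 target genes passed over all genes (4 up and 8 down adjusted over the list alone, camera adjusted p = 0.969). The same held for 19 adrenergic signalling genes (1 up and 1 down adjusted over the list alone, camera adjusted p = 0.969) and 14 clock genes (0 up and 0 down adjusted over the list alone, camera adjusted p = 0.620). Without control replicate 1 these lists had more calls in both directions or downward: 10 up and 8 down for unfolded protein, 2 and 8 for heat shock, 3 and 8 for fatty acid oxidation, 4 and 6 for p53, 4 and 4 for guidance, 5 and 6 for interferon, 5 and 11 for NRF2, 2 and 4 for adrenergic and 0 and 2 for clock genes. The median and the direction of the camera test differed in sign for the hypertrophy, NRF2 and adrenergic lists, and the mean and that direction for the gap junction, NRF2 and adrenergic lists. Camera compares a list with the other tested genes, so its direction is relative to them and not to 0. The median log2 fold change over all tested genes was -0.04.

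Markers of other heart cell types were mostly at or near 0. Of 10 fibroblast markers 1 was tested, the actin-severing gelsolin gene Gsn, which fell from 245 ± 18.1 to 203 ± 7.07 FPKM. Of 10 endothelial markers 3 were tested, Pecam1, Egfl7 and Flt1, and 0 passed. Of 9 smooth muscle and pericyte markers 1 was tested, Smtn, at 13.6 ± 1.36 and 13.2 ± 0.196 FPKM.

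Other than Cxcl3, every called gene had an adjusted p between 0.0435 and 0.0498, and the counts rested on single libraries: without control replicate 1 they became 1160 higher and 1948 lower, and without control replicate 2, control replicate 3, tachypaced replicate 1, 2 or 3 they became 1, 1, 2, 3 and 2 higher and 0, 0, 0, 0 and 1 lower by limma-trend, although 763 to 958 higher and 1197 to 1782 lower genes had an unadjusted p under 0.05. The share of called genes that were higher was 41.6%, and it became 60.2% with median of ratios scaling, 76.5% of 17 calls with quantile normalization and 21.3% with a common total per library, while without the filter on low values 0 genes passed limma-trend (1457 higher and 2031 lower at an unadjusted p under 0.05).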

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

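The library weights, the adjusted p threshold of 0.1 and the estimated correlation were chosen after seeing the data. No named gene and none of the 12 lists past camera reversed its direction, and the cause of the changes below was not tested unless stated. Against 238 genes higher and 334 lower, the counts were 0 and 0 without the filter on low values (15992 genes tested, smallest adjusted p 0.0588, 1457 and 2031 at an unadjusted p under 0.05), 13 and 4 with quantile normalization, and 2 and 0 by limma without the trend (1077 and 1980 unadjusted). Array weights, which gave control replicate 1 a weight of 0.31, led to 1154 and 1942, and a threshold of 0.1 to 724 and 1250. An absolute log2 fold change of at least 1 left 6 and 0, by the construction of that filter (1116 and 2008 genes had an unadjusted p under 0.05). Genes lower numbered 178 with median of ratios scaling and 925 with a common total per library, while genes higher stayed within 1.5 times there (269 and 251).

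Leaving out each library in turn gave 1 to 1160 genes higher and 0 to 1948 lower; the highest values came without control replicate 1, which kept all 572 called genes. The replicate numbers gave no clear pairing of the libraries: deviations from the group means correlated at 0.06, -0.03 and 0.16 for numbers 1, 2 and 3, and not every library correlated best with its own number. With 3 libraries per group this cannot exclude a pairing. With the replicate block the counts were 334 and 591, and 12 lists passed.

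The 12 lists past camera became 0 with an estimated correlation and 10 to 12 under the other alternatives, among them 10 at a minimum mean of 5 FPKM, where 22 lists had enough members. The ribosomal protein list no longer passed under quantile normalization (adjusted p 0.239) and the matrix list without control replicate 1 (0.0784). Of 67 named genes tested, 67 kept their side of the threshold with the common total, 66 with a pseudocount of 0.1, 61 with robust hyperparameters, 52 with median of ratios scaling, 9 with quantile normalization, 5 without the trend and 4 without the filter on low values. Leaving out control replicate 1 kept 65, and leaving out any other library kept 5. Kcnj2, Atp2a2, Fos and Ccl2, which were not called, count as kept where they stayed uncalled. Without the filter 0 genes passed, so only uncalled genes were kept there. Cxcl3 was the only called gene that stayed called when a library other than control replicate 1 was left out. Depth is unknown, so its part in these limits cannot be given.

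Of the lists that did not pass camera, 6 reversed direction under some alternative, without passing. These were guidance without the filter on low values (adjusted p 0.950), at a minimum mean of 5 FPKM (0.899) and with array weights (0.899), NRF2 without the filter (0.786), with quantile normalization (0.537), a common total (0.963) and array weights (0.657), and adrenergic signalling without the filter (0.768), with quantile normalization (0.790) and a common total (0.963). Leaving out single libraries reversed these and the gap junction, nuclear oxidative phosphorylation and fatty acid oxidation lists, with adjusted p over all libraries left out of 0.748 to 0.990 for guidance, 0.568 to 0.990 for NRF2, 0.821 to 0.990 for adrenergic signalling, 0.838 to 0.990 for gap junction, 0.106 to 0.979 for oxidative phosphorylation and 0.474 to 0.990 for fatty acid oxidation. By fry, which does not take the other genes as reference, the gap junction, NRF2 and adrenergic lists had the direction opposite to camera.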

Other observations

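The families in this paragraph, and the tests on control replicate 1, on Cxcl3 and on the counts of genes under other splits, were chosen only after the results were seen. The test of the gene lists under other splits was set before. The tests of cell identity were set after a first look at the table had shown the pattern, and before their further genes were looked at. Of 38 genes tested under histone-like symbols, 5 rose, 0 fell and 33 did not pass. They take in H13, a histocompatibility gene and not a histone, which did not pass (log2 fold change 0.07). No set test was run on this or the other families here. Those that rose included H1f0, a linker histone of non-dividing cells (152 ± 28.7 to 221 ± 18.9 FPKM, SD, n = 3 each), and H3f3b, a replication-independent histone (163 ± 12.2 to 251 ± 44.7 FPKM), while 32 of the 38 had a positive log2 fold change (32, 32 and 29 under median of ratios, quantile and common-total scaling). Of 12 tubulin genes 2 fell, Tubb5 (213 ± 39.4 to 146 ± 7.09 FPKM) and Tubb4b, and 0 rose. The log2 fold change was negative for 11 of the 12, also under each of these scalings. The calls did not hold as well: 0, 0 and 4 tubulin genes fell under median of ratios, quantile and common-total scaling.

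Of 6 tested MHC class II genes 2 rose and 0 fell, H2-Aa (4.39 ± 1.02 to 7.55 ± 0.242 FPKM) and H2-Eb1 (15.3 ± 2.29 to 22.9 ± 2.22 FPKM), while Cd74, H2-DMa and H2-Oa were among those that did not pass. Of 7 tested Serpinb genes 3 rose and 0 fell, among them Serpinb9, a granzyme B inhibitor (5.18 ± 0.694 to 9.21 ± 1.38 FPKM). Under quantile normalization 0 genes of these 4 families passed limma-trend, where 17 of all tested genes did (1443 higher and 1565 lower at an unadjusted p under 0.05). Without control replicate 1, 17 genes of the histone set, which takes in H13, rose and 3 fell, and 7 tubulin genes fell and 1 rose. In the same setting 2 MHC class II genes rose and 0 fell, and 4 Serpinb genes rose and 1 fell.

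The libraries are labelled as an atrial cardiomyocyte line but hold macrophage transcripts. Macrophages mixed into HL-1 cultures would leave the abundant cardiomyocyte transcripts in place, yet the highest library median over 20 further cardiomyocyte genes was 0.004999 FPKM, with Myh6 and Actc1 at 0. Estimates that failed and were listed as 0 would also have struck ubiquitous genes, and 0% of 50 such genes had a mean below 0.1 FPKM. A candidate explanation is that all 6 libraries come from macrophage-lineage cells, since the lowest library median over 25 further myeloid genes was 34.2 FPKM, with Lcp1 at 320, Lgals3 at 264 and Laptm5 at 220 FPKM as means of 6 libraries. Where such cells entered (culture, sample handling or labelling) was not tested, nor whether the table belongs to other samples than those labelled (the series title concerns macrophages), in which case its columns would not carry these groups and no contrast given here would hold.

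Control replicate 1 lay at 0.657 between the other controls and the tachypaced libraries as a median over genes, where tachypaced libraries, each left out in turn, lay at 0.998, 1.05 and 0.788, so its distance of 0.131 to the lowest was within their SD of 0.137. On the averages of the 11 lists that passed camera without it, however, it ran from -0.2831 (mitochondrial genome) to 0.888 (hypoxia and glycolysis). On the former its 95% bootstrap interval ended 0.605 below the lowest tachypaced library left out (0.576, with an SD of 0.416). Of the 11 lists, 1 lay that far off on the log2 and FPKM scales and with each baseline, by a rule set after the data were seen. The other lists did not in every setting. Resting on the most extreme list, the test cannot decide whether this is a tachypaced library under a control label. RNA of tachypaced cells mixed in should give a common share. The intervals of these lists lay apart by 0.8187 on the FPKM scale, on which a mixture is additive (0.698 and 0.835 with control replicate 2 or 3 alone as baseline, and 0.797 on the log2 scale). In the other libraries any lists lay apart by 0.0495 to 0.264, taken the same way on either scale. The mitochondrial genome list was the lower one in every setting. This goes against a share common to that list and the hypoxia and glycolysis list, but with 1 list deciding it cannot exclude a mixture. Medians over the genes that separate the groups, tried before and without the mitochondrial list, lay apart by at most 0.180 on the FPKM scale (0.206 and 0.145 with a single control). These gaps, between the chemokine and the cholesterol and fatty acid synthesis lists, exceeded the mean half-widths of their intervals (0.0995, 0.103 and 0.0946). On the log2 scale the medians lay apart by at most 0.0347, less than the mean half-width of their intervals (0.119). Such medians were not taken for the other libraries. All these intervals cover genes and not libraries. A wrong label and a mixture stay open. A different state of this culture, or either of the former joined to another difference, was not tested and stays open too.

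Cxcl3 changed more than any other called gene, with an adjusted p under 0.05 in 15 of 16 alternatives (0.0588 without the filter on low values, range 7.87e-06 to 0.0588; log2 fold change 3.14 to 5.13). Reads assigned to a neighbouring chemokine gene in the control libraries could produce it. Of 19 genes within 1 Mb, 0 were lower in all tachypaced libraries by at least 5 FPKM, but Cxcl2 stood at 793 ± 146 FPKM in control libraries and 121 unplaced models were above 5 FPKM there, so a partner may be hidden and this cannot be told apart from regulation. Cxcl3 may instead be part of the graded chemokine increase: in control replicate 1 its position was 0.1024, against 0.314 to 0.567 for Ccl3, Ccl4, Cxcl2, Csf3, Il1rn, Lcn2 and Saa3, but at 0.688 FPKM in that single library it is too close to 0 to decide. Of 12 genes that ranged by over 3 on the log2 scale between libraries, 10 did not follow the groups, among them Evi2b, Guca1a and Ramp2.

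With 10 splits of the 6 libraries into 3 and 3 no share under 0.05 can be reached. The real split gave 238 genes higher, 334 lower and 12 lists, and the highest of the other splits gave 1, 1 and 11. In each case 1 split, the real one, gave a result as large. The other splits passed 0, 1, 4, 6, 0, 9, 11, 10 and 9 lists by camera at the preset correlation. Groupings that mixed control and tachypaced libraries thus often came near the real count of lists. The counts of 11, 10 and the last 9 came from splits that grouped control replicate 1 with tachypaced libraries only, toward which it lay. Splits that joined it to another control passed 0, 1, 4, 6, 0 and 9. The counts are therefore no general rate of false calls under arbitrary splits.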
